A study of Caenorhabditis elegans with 12 samples.

How the data were processed

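Wild-type N2 Caenorhabditis elegans hermaphrodites were raised from the egg at 20 °C and then kept for 48 h at 25 °C, with or without 10 mM lithium chloride (LiCl), per the labels' protocols. There were 6 control and 6 LiCl samples, described by the submitters as separately grown and harvested. Each sample was a pellet of 50 picked worms. Per the labels, its RNA was amplified in a single round, 5 µg of amplified RNA was labelled with Cy5, and it was hybridised with Cy3-labelled RNA pooled from N2 worms of mixed stages. Each of the 12 samples was hybridised to its own 2-colour array, and no dye swap is named.

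The deposited table gives a processed log ratio of each probe on each array, read here as log2. The authors' normalization, the array platform's software and any filter on spots are not given in the sources used here. The log base and a scale factor are not stated, and the values do not settle them. The interquartile range was close to 1.34 on every array, against 1.349 for a standard normal distribution, so each array may have been divided by its own spread before deposit. Differences are therefore given in deposited log ratio units, and no fold changes are given. Array medians lay between 0.018 and 0.044. The direction, sample over reference, is likely rather than stated. It rests on the dyes in the labels and on levels: all 4 maternal and oocyte genes lay above 0, and 23 of 26 neuropeptide genes lay below 0.

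The table holds 22370 probes, of which 21839 had a value on all 12 arrays. A gene name was available for 8757 probes (8187 genes) through the platform annotation, and no probe carried several names. The other 13613 probes are unnamed here. Names were updated through gene identifiers to the WBcel235 annotation, which matched 8724 named probes, and 33 kept the older name. Most classical gene names are absent among the named probes. The lithium-linked genes gsk-3, ttx-7, bpnt-1, lsd-1, daf-16 and sod-3, chosen for naming whatever their result, carry no named probe and were not analysed here.

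Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates) on the values as deposited, because the array medians lay within 0.1 of one another. Probes needed values on at least 4 arrays of each group, a condition that all probes met. P-values were adjusted by the Benjamini-Hochberg method over all probes, with a threshold of 0.05. Adjusted p-values of single probes in the text come from this fit, and standard errors (SE) are the moderated ones. Gene lists of at least 3 measured genes, with 1 probe per gene, were tested with limma's camera at a preset inter-gene correlation of 0.01. Beside it stand camera with an estimated correlation, fry, and an exact permutation test of the mean of the list per array over all 924 assignments. For each, p-values were adjusted over the 2 testable lists fixed beforehand, and separately over the 37 lists added later. Adjusted values of the 2 families therefore cannot be compared directly. The smallest p this exact test can give is 0.00216.

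The groups, tests, alternatives, rule for named genes and 34 gene lists were fixed before the data were examined. Only 2 of those 34 lists had 3 measured genes, 7 had 1 or 2, and 25 had none. For this reason 37 further lists were built from the names the probes carry, after the table was opened and before any group difference was computed. The genes named are the 10 probes with the largest positive and the 10 with the largest negative difference among called, fully measured, named probes, and up to 4 called members of each list, smallest p first. Members of the further lists go beyond the rule as first written, and other genes named outside it were chosen after their values were seen.

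The code was tested on simulated arrays of 22370 probes with the spread of the real ones. Of 50 probes shifted by each size, 2% were recovered at 0.5, 26% at 1, 86% at 2 and 88% at 3 log ratio units, with 3 false calls among 104. Few probes were shifted, so the adjusted threshold was stricter than with the 1789 calls in the real data. These shares may therefore understate recovery in the real comparison. Arrays simulated without a change gave 0 calls. Each probe was drawn independently from a normal distribution, without deviations shared by probes or arrays. The false calls there therefore check the code and say little about false calls in the real data. The number of arrays limits the precision, and spot intensities were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The alternatives tried were other normalizations, filters, variance models, array weights, a replicate block, other thresholds and list tests, and leaving out arrays.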

Results

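Transcript levels were measured on 12 arrays, 6 of control worms and 6 of worms kept for 48 h on 10 mM LiCl, each against the same mixed-stage reference RNA. Between 16 and 150 of the 22370 probes had no value on a given array. Across probes, the correlation between arrays had a median of 0.731 within the control group, 0.679 within the LiCl group and 0.628 between the groups. The first principal component held 19.8% of the variance and separated the groups, with all 6 control arrays below 0 and all 6 LiCl arrays above it.

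The comparison asks which transcripts differ in level in wild-type worms after LiCl. In LiCl worms 1006 probes rose and 783 fell. The largest named increases were in W09D6.4, F22F1.2 and F19B10.4, and the infection response genes irg-4 and irg-5 and 5 carboxylesterase genes rose as well. The largest named decreases were in F46A9.1, Y106G6H.9 and Y60A9.3. In a list of translation initiation factors built from gene names 3 genes fell, near the threshold (adjusted p between 0.0368 and 0.0468). The sizes below are differences in deposited log ratio, LiCl minus control, with n = 6 arrays per group, or fewer where a probe lacked a value. The direction of the ratio is likely rather than stated, and with the ratio turned every rise here would read as a fall.

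The 1789 changed probes made up 8.0% of those tested, and 56.2% of them were higher in LiCl. The median difference over all probes was 0.019, and the median size among the changed probes was 0.97. A difference of at least 1 was found for 550 higher and 300 lower probes. The control and LiCl values did not overlap at all for 1478 probes, whereas chance alone gives 0.216% of probes, or 48.4. Of the named probes 8.11% were called, and of the unnamed probes 7.93%. The calls covered 445 named genes that rose and 252 that fell. Of 467 genes with several probes, 48 had a called probe, and in 12 of these all probes were called. The probes of 42 of the 48 shared 1 direction, and none had probes called in opposite directions. Over the 467 genes, the differences of the first and second probe correlated at 0.395.

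**Figure D1:**
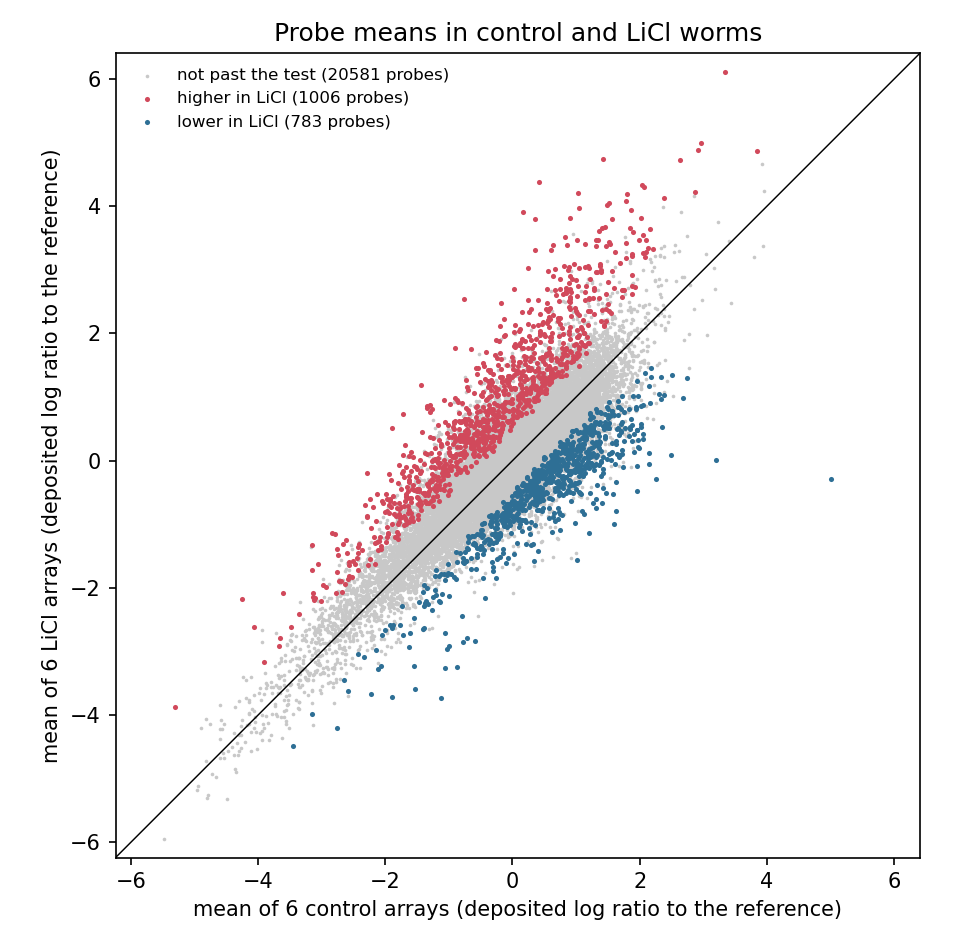
Mean deposited log ratio of each probe on the 6 LiCl arrays (vertical axis) against the 6 control arrays (horizontal axis), with the line of equality. The 1006 probes that rose lie above the line and the 783 that fell below it, and the isolated point at the far right is an unnamed probe with a difference of -5.30.

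W09D6.4 showed the largest named increase. On its first probe it went from 0.42 ± 0.57 (SD, n = 6) in controls to 4.38 ± 0.67 (SD, n = 6) in LiCl, a difference of 3.96 ± 0.34 (SE, adjusted p = 6.99e-05), and on the second the difference was 3.46 ± 0.52 (SE). F22F1.2 rose by 3.74 ± 0.41 (SE) and F19B10.4 by 3.33 ± 0.41 (SE). Y38H8A.2 (2.96), C17C3.5 (2.76), Y38E10A.22 (2.75), ZK930.4 (2.70) and irg-4 (2.68) followed. T24A6.7 differed by 2.79 ± 0.67 (SE, adjusted p = 0.0244) with overlapping groups, and its adjusted p lay above the threshold, between 0.0509 and 0.0571, when control replicate 3, 4 or 6 or LiCl replicate 1 was left out. For the other 9 of these 10 probes every LiCl array lay above every control array.

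F46A9.1 fell most among the named genes, from 3.20 ± 1.16 (SD, n = 6) to 0.01 ± 0.43 (SD, n = 6), a difference of -3.19 ± 0.46 (SE, adjusted p = 0.00133). Next came Y106G6H.9 (-2.44), Y60A9.3 (-2.41), ZK813.1 (-2.37), W01C9.2 (-2.34) and R03G8.6 (-2.25). Y62H9A.4 (-2.19), C04H5.7 (-2.07), W02D9.6 (-2.05) and Y46G5A.28 (-1.96) fell as well. In all but Y46G5A.28 the 6 LiCl arrays lay below the 6 control arrays. The functions of these sequence-named genes are not stated in the annotation used here.

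The largest difference of all was in an unnamed probe, number 12424. It had a mean of 5.01 ± 0.62 (SD, n = 6) in controls and -0.29 ± 0.25 (SD, n = 6) in LiCl, a difference of -5.30 ± 0.27 (SE, adjusted p = 1.27e-06). Another unnamed probe, 20073, fell by 2.60, while unnamed probes 365 and 8231 rose by 3.31 and 3.18.

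**Figure D2:**
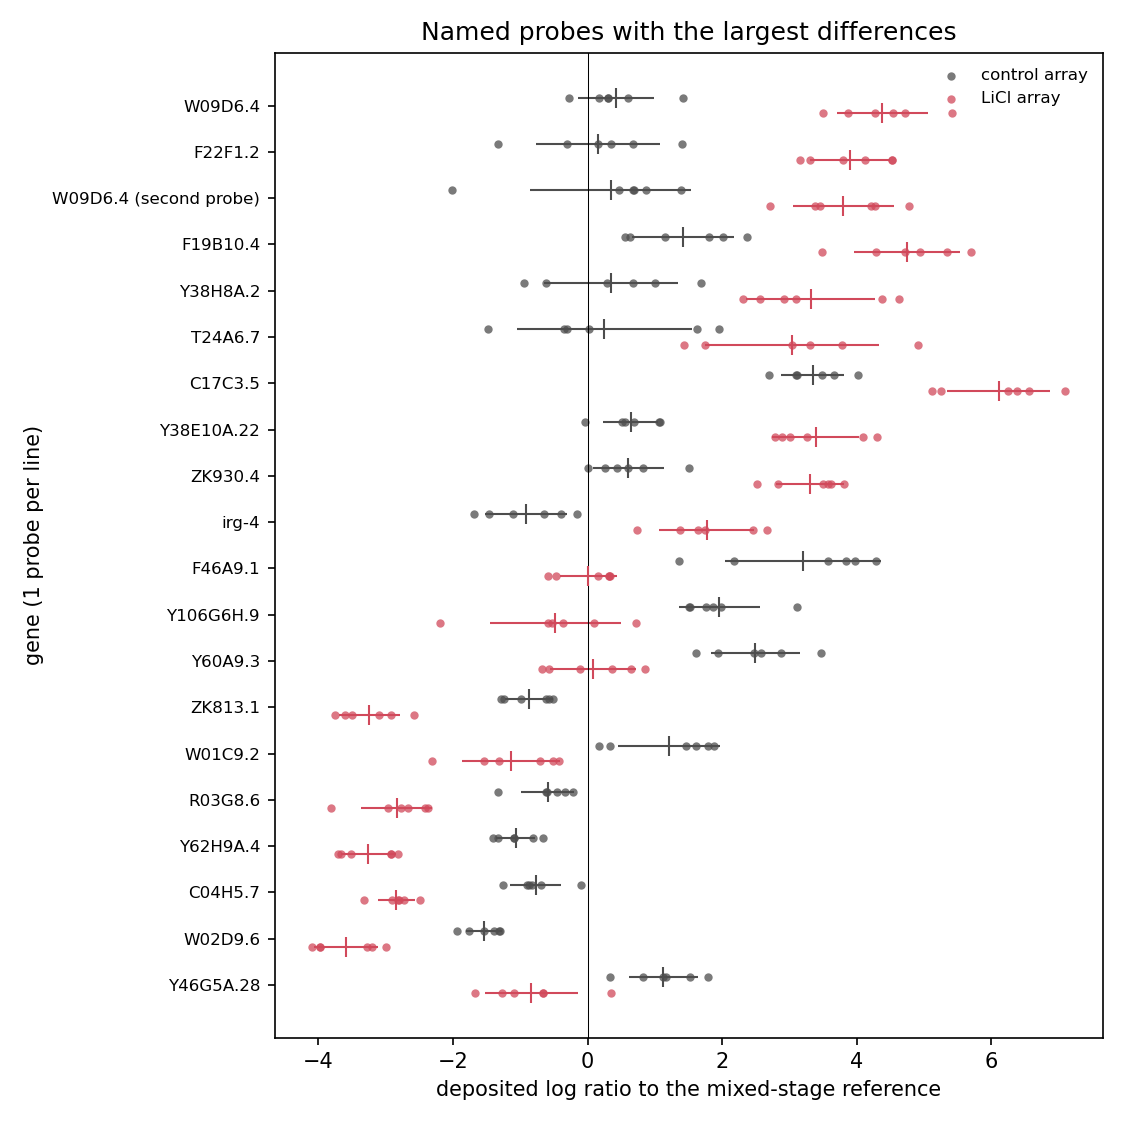
Deposited log ratio (horizontal axis) of the 20 named probes with the largest differences, 1 probe per line. Points are single arrays, grey for control and red for LiCl, and ticks and bars are group means and SD (n = 6). The points of W09D6.4 and F46A9.1 do not overlap between groups, whereas those of T24A6.7 do.

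Among the innate immune effectors, 2 of 5 measured genes rose and none fell, and the count was also 2 when adjusted over the list alone. irg-4 rose by 2.68 ± 0.36 (SE) and irg-5 by 2.11 ± 0.25 (SE), whereas irg-8 (-0.42), spp-24 (0.30) and spp-31 (-0.05) did not pass the test. The mean of the 5 genes was higher by 0.92 in LiCl, with all 6 LiCl arrays above every control array (exact permutation test, p = 0.00216, adjusted p = 0.00433 over 2 lists). Against other genes the shift was not past the threshold (camera, adjusted p = 0.0583, and adjusted p = 0.207 with an estimated correlation). It passed without control replicate 2 (adjusted p = 0.0496) or 4 (0.0433) or LiCl replicate 2 (0.0443). These values were adjusted over 2 lists only. The unadjusted camera p was 0.0291, above the 0.00356 of translation initiation factors, which became 0.132 when adjusted over 37 lists. Of 24 genes of the pals family, which belongs to the intracellular pathogen response, pals-2 rose (0.66 ± 0.18, SE) and no other member passed the test. When adjusted over the list alone none did, and the camera adjusted p of the list was 0.203.

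Of the cell type and stage markers fixed beforehand, only the pharynx list could be tested. Of its 3 genes phat-8 rose (1.01 ± 0.26, SE) and pqn-15 fell (-0.96 ± 0.19, SE), the same count as when adjusted over the list alone. The mean (0.14) and median (0.38) were positive and camera's direction was downward, with an adjusted p of 0.999. Genes of fixed lists with fewer than 3 measured members were not called, among them ugt-66 (0.96, adjusted p = 0.186), gldc-1 (0.69, adjusted p = 0.084) and rpl-37.1 (0.27, adjusted p = 0.503).

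Carboxylesterase genes, grouped by name, had 5 of 31 members higher and none lower. cest-15 rose by 2.22 ± 0.23 (SE), cest-1.1 by 1.61 ± 0.29 (SE), cest-1.2 by 0.86 ± 0.24 (SE) and cest-2.2 by 0.80 ± 0.19 (SE). The claudin-like family had 3 of 17 members higher, clc-9 (1.45), clc-25 (1.12) and clc-19 (1.01), and none lower. Solute carriers went both ways, with 3 of 32 higher and 4 lower. slcr-46.2 rose by 2.00 and mfsd-8.3 by 1.54, while mfsd-12 (-1.304) and slc-30A5, of the zinc transporter family (-0.75), fell. When adjusted over the list alone, the counts were 6 higher and 1 lower for carboxylesterases, 3 and 0 for the claudin-like family, and 6 and 4 for solute carriers. Camera adjusted p-values were 0.168 for carboxylesterases, 0.433 for the claudin-like family and 0.531 for solute carriers.

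In the list of translation initiation factors, built from gene names, 3 of 7 genes were lower and none higher. These were eif-4A3 (-0.72 ± 0.19, SE), whose human counterpart belongs to the exon junction complex, eif-2Bepsilon (-0.62 ± 0.17, SE), a subunit of the nucleotide exchange factor eIF2B, and eif-2gamma (-0.50 ± 0.14, SE), a subunit of eIF2. The mean of the list was -0.34, with 5 of 6 LiCl arrays below every control array (exact permutation test, adjusted p = 0.04, camera adjusted p = 0.132, and adjusted p = 0.574 with an estimated correlation). Of the germline genes, enri-2 (-0.96), the synaptonemal complex gene syp-6 (-0.77), the germ granule gene mip-1 (-0.72) and the maternal gene memi-2 (-0.63) fell. So did rev-3 (-0.81), which encodes the catalytic subunit of DNA polymerase zeta. In the germline small RNA and germ granule list 2 of 20 genes fell (4 when adjusted over the list alone) and none rose, in the meiotic list 1 of 8, and in the maternal and oocyte list 1 of 4. The means of the first 2 lists, -0.18 (exact permutation test, adjusted p = 0.0534, camera adjusted p = 0.138) and -0.17 (exact permutation test, adjusted p = 0.385, camera adjusted p = 0.17), did not pass. The maternal and oocyte mean was -0.31 (exact permutation test, adjusted p = 0.0481, camera adjusted p = 0.168, and adjusted p = 0.577 with an estimated correlation). Of 15 sperm genes, spe-51 rose by 2.07 and spe-57, which had no value on control replicate 1, fell by 0.88.

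**Figure D3:**
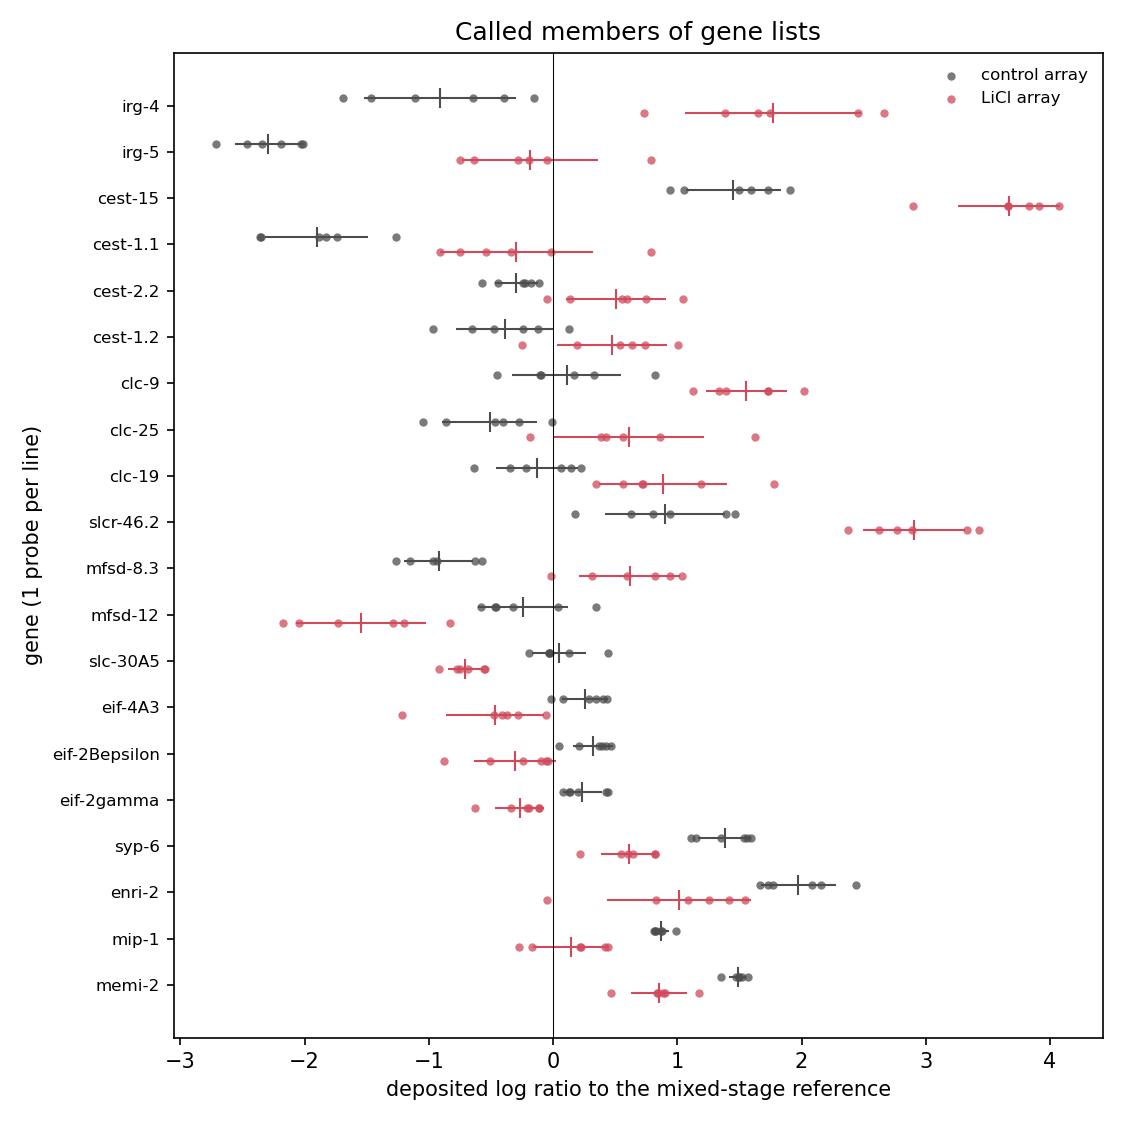
Deposited log ratio (horizontal axis) of 20 called members of the gene lists, 1 probe per line. Points are single arrays, grey for control and red for LiCl, and ticks and bars are group means and SD (n = 6). Between the group means, cest-15 differs by 2.22 and slc-30A5 by -0.75.

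Fatty acid oxidation genes had no called member among 12, against 4 higher when adjusted over the list alone, while their mean was 0.32 higher in LiCl, with 5 of 6 LiCl arrays above every control array (exact permutation test, adjusted p = 0.04, camera adjusted p = 0.168, and adjusted p = 0.574 with an estimated correlation). None of 24 respiratory chain subunits, 26 ribosome biogenesis genes or 19 genes of N-glycosylation and GPI anchor synthesis passed the probe test. None of 5 inositol and phosphoinositide enzyme genes did either, inpp-4B being nearest (-0.73 ± 0.22, SE, adjusted p = 0.0567), whereas 1 was lower when adjusted over the list alone. With camera, 0 of the 2 fixed and 0 of the 37 further lists passed, whereas 1 and 10 had an unadjusted camera p under 0.05, fry called 1 and 8, and the exact test 1 and 5.

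The count of changed probes was 847 on the 8 arrays of higher weight, 622 with the lower part of probes by overall spread left out, and 1181 without control replicate 4. On those 8 arrays 35 of the 73 named probes passed, with 2 innate immune effectors, 2 carboxylesterases, 1 claudin-like gene and 2 solute carriers higher and 1 solute carrier lower. Differences there were -0.70 in syp-6, -0.62 in memi-2, 1.99 in spe-51 and -0.45 in spe-57. They were -0.57 in eif-4A3, -0.46 in eif-2gamma and -0.44 in eif-2Bepsilon. No translation initiation factor, meiotic, maternal or sperm gene was called there. Nor were phat-8 (1.03, adjusted p = 0.142), pals-2 (0.49, adjusted p = 0.292), enri-2 (-0.72, adjusted p = 0.129), mip-1 (-0.50, adjusted p = 0.109) and rev-3 (-0.71, adjusted p = 0.0803). In contrast, pals-31 (-1.05) was lower there. Higher there were picd-1 (1.47), from the germline small RNA and germ granule list, and acs-25 (1.0997), from the fatty acid oxidation list. Both lists were built from gene names, and the function of picd-1 was not checked here. None of these 3 genes was called on all 12 arrays. Of the 20 named probes with the largest differences, 19 passed under all 23 settings that gave them a value. This decides little, since they had been picked as the largest called differences on these same arrays. Arrays also differed in their upper tail, with a 95th percentile of 1.51 ± 0.035 (SD, n = 6) in control and 1.67 ± 0.083 (SD, n = 6) in LiCl (exact permutation test, p = 0.00216, the smallest it can give, adjusted p = 0.013 over 6 measures). The interquartile range was lower in LiCl, 1.337 ± 0.0039 (SD, n = 6) against 1.343 ± 0.00078 (SD, n = 6; exact permutation test, p = 0.0108, adjusted p = 0.0324). If each array was divided by its own spread before deposit, this range tells little about the worms. The other 4 measures did not pass.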

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

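The splits of the 8 arrays of higher weight and the test of a scale factor were chosen after the result was seen.

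Single arrays stood far from the other 5 of their group in 15 of 158 group comparisons, where chance gives about 1 in 20, or 7.9. LiCl replicate 6 lacked 150 probes, against 25 to 38 on the other LiCl arrays. Control replicate 4 stood apart in R03G8.6 (-1.325), nssp-72 (-3.722), lido-7 (1.863) and txt-19 (-1.268). Control replicate 5 did so in the second W09D6.4 probe (-2.01), control replicate 1 in Y106G6H.9 (3.115), and control replicate 2 in mip-1 (0.9921) and nssp-18 (-0.1396). Among LiCl arrays, replicate 1 stood apart in ttbk-3 (4.862) and eif-4A3 (-1.216), replicate 2 in gtf-2H2C (-0.2992) and erd-2.2 (0.2109), and replicate 6 in timm-17B.2 (2.004) and cest-15 (2.899). LiCl replicate 1 also had the lowest array weight (0.524) and the highest 95th percentile (1.827). It was the highest LiCl array in irg-4, irg-5, cest-15 and cest-1.1, and the lowest in eif-2Bepsilon, eif-2gamma, syp-6 and memi-2. Other LiCl arrays lay farthest from the controls in F22F1.2, C17C3.5, enri-2 and other genes. Without LiCl replicate 1, 1527 probes changed and 18 of 73 named probes fell short of the threshold.

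Chance assignment of the arrays is argued against for the number of changed probes, 1789. Only 1 of 100 splits of the 12 arrays, the real one, gave as many, and the highest of the others gave 0. No share smaller than 1 of 100 was possible with the splits drawn. The differences of consecutive probe numbers correlated at 0.0361, which decides nothing about place on the slide, as no source used here ties these numbers to places. Noise on the 4 arrays of lowest weight as the source of all calls is argued against only weakly by the 8 other arrays. Weights were computed with the groups known, which favours the real split. On the 8 arrays 1 of 56 splits, the real one, gave as many as its 847 changed probes, and the highest other gave 0. All 1789 probes kept their direction there (share 1), which decides little, since those probes had been called on these arrays too, and noise behind part of the calls stays open, as 709 of them were called there. Place on the slide and an effect of LiCl stay open, and no batch of labelling or scanning is named, so none was tested.

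No gene list passed camera, so all 100 splits gave as many fixed lists and all 100 as many further lists, with at most 1 and 3 lists in a split other than the real one.

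A larger scale factor alone is argued against for the higher 95th percentile of the LiCl arrays. A factor would leave the distance of this percentile from the median, divided by the interquartile range, alike in both groups. This quotient was 1.096 ± 0.029 (SD, n = 6) in control and 1.232 ± 0.065 (SD, n = 6) in LiCl, a difference of 0.136 (exact permutation test, p = 0.00216). A step of labelling or scanning that acts on strong signals stays open, as does an effect of LiCl, since spot intensities were not used.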

How the results depend on the processing

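The further gene lists, the setting with 8 arrays and the test of matchings were chosen after seeing the data. The counts of changed, higher and lower probes (1789, 1006 and 783) stayed within 1.5 times under 11 of 14 settings other than leaving out 1 array. Leaving out the lower part of the probes by spread gave 622, 432 and 190, though 1127 of the 1789 lay in the part kept; the pooled spread was then estimated from more variable probes. An adjusted p under 0.10 gave 2836, 1554 and 1282 by its construction. The 8 arrays of higher weight (without control replicate 5 and LiCl replicates 1, 2 and 6) gave 847, 528 and 319, of which 709 were shared, with fewer arrays. Leaving out 1 array gave 1181 to 1600 changed, 697 to 976 higher and 479 to 681 lower probes; the lowest came without control replicate 4 (1181 and 484 lower) and control replicate 6 (479 lower). With camera, adjusted over the 2 fixed lists, 1 list, innate immune effectors, passed with quantile normalization and with array weights. This list also passed without control replicate 2 or 4 or LiCl replicate 2, so leaving out 1 array gave 0 to 1 lists. Its camera adjusted p ranged from 0.0433 to 0.207. Fry called 1 fixed and 8 further lists and the exact test 1 and 5. Unlike camera, these do not compare a list with other genes, and the reason for the differing counts was not tested. No fixed list had 3 genes left under the spread filter. Requiring values on 2 arrays per group removed no probe.

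The replicate numbers were not treated as pairs, since same-numbered deviations correlated above 0.1 in 1 of 6 pairs. The data hold a hint of pairing, with a mean correlation of 0.0497 that 11 of 720 matchings of the arrays reached (permutation p = 0.0153), and 6 of 12 arrays correlating best with their own number, against 2 on average over matchings (permutation p = 0.0389). With a replicate block, 1393 probes changed, 20 of 73 named probes had an adjusted p above the threshold, and T24A6.7, with a difference of 2.79, had an adjusted p of 0.0509. Of 73 named probes, none reversed in 1655 comparisons with other settings, which decides little, since they had been called on these same arrays. In 344 comparisons a probe fell short of the threshold, mostly with fewer arrays. Signal over background is not known here.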

Other observations

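The tests of gonad share, of counts and signs of adjacent called genes and of all 20 divisions of the controls were chosen after the result was seen, as were the adjacent genes named here.

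Several nematode gene families with little annotation also held called members. Such counts alone do not show a response of a family, as 8.11% of all named probes were called. The nssp family had 4 of 55 genes higher and none lower, among them nssp-72 (1.31), nssp-52 (1.03) and nssp-37 (1.02), with a camera adjusted p of 0.17. None of the 4 was called on the 8 arrays of higher weight, where their differences lay between 0.91 and 1.48. In the idp families 3 of 28 rose, led by idpp-2 (2.25 ± 0.27, SE) and idpp-7 (1.16 ± 0.16, SE), and in the txt family 2 of 15, txt-19 (1.14) and txt-4 (0.94), against 5 when adjusted over the list alone. On those 8 arrays idpp-2, idpp-7 and txt-19 were called. The means of both lists were higher on all 6 LiCl arrays than on every control array (exact permutation test, adjusted p = 0.04 each), with camera adjusted p of 0.263 and 0.132, and 0.577 and 0.574 with an estimated correlation. The gtnt family went both ways, with 1 of 54 genes higher, gtnt-49 (2.67), and 2 lower, gtnt-27 (-1.32) and gtnt-1 (-1.15). Its camera adjusted p was 0.606. On the 8 arrays gtnt-49 (3.26) was higher and, of the lower ones, gtnt-16 (-0.75) was called in place of gtnt-27 and gtnt-1.

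Differences of genes next to each other in the WBcel235 annotation correlated more than those of reordered genes. Across 3334 adjacent pairs of named genes, which are not independent replicates, the correlation of their differences was 0.117 (Spearman's rho 0.0999), above the highest of 10000 reorderings (0.0721, permutation p = 1e-04, the smallest they can give). It was 0.0475 with 1 gene between them and 0.0086 with 4. Both genes were called in 42 pairs, against 24.32 on average in the reorderings (one-sided permutation test, p = 7e-04). Of the 42, 29 shared a sign, against 22.74 on average when the called genes were reordered among themselves (one-sided permutation test, p = 0.0366), such as Y62H9A.3 (-1.91), Y62H9A.4 (-2.19), stha-3 (-1.65) and ule-5 (-1.72) in a row. Shared control of neighbours may account for this, while hybridisation between tandem copies stays open, as probe sequences were not used.

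Of the ule genes, named for expression in the uterine lumen, ule-3 (-1.65) and ule-5 (-1.72) fell. A fall of the set is argued against by ule-1 (0.13, adjusted p = 0.812) and ule-4 (-0.19, adjusted p = 0.648), of which 0 passed the test. A lower share of gonad tissue was a candidate explanation. The 25th percentile of 32 genes in the germline, meiotic and maternal lists, built from gene names, was -0.445. It lay above the ule median of -0.92, so most of these genes fell less than ule-3 and ule-5. This cannot decide about gonad tissue as a whole, since germline genes need not follow the uterus. The ule median also lies between ule-3 and ule-5, which fell, and ule-1 and ule-4, which did not pass the test. A response of the ule genes themselves was not tested.

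A shift of the LiCl worms along the axis of the mixed-stage reference stays open. The correlation of level and change across probes was -0.0644 with the level from control replicates 1 to 3 and the change from the others, and -0.176 the other way round. Over all 20 such divisions of the controls it ran from -0.186 to -0.053, all below 0, 6 within 0.1 of 0 and none beyond 0.2 in size. By the rule set beforehand, a correlation within 0.1 of 0 in either direction of the first division argues against such a shift, and -0.0644 met it. That verdict depends on the division, as only 6 of the 20 lay within 0.1. The bound was too narrow for this spread (SD 0.0399 over divisions). The question was therefore left open after the values were seen, against the rule. With the same controls in both it was -0.246, where shared values alone push it below 0.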
